A study of Mus musculus with 4 samples.

How the data were processed

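Phospho-CREB chromatin immunoprecipitation libraries of MC3T3-E1 cells were compared between 1 h of DMSO vehicle and 1 h of 100 nM forskolin, with 2 libraries per treatment. Groups and replicate numbers were taken from the sample titles, and the labels call the libraries biological replicates. An input library of another series is named in the labels and was not used here. The deposited values are 1 peak list per library, so peaks had been called per library and not on pooled reads. Reads were aligned with Bowtie and HOMER was used, per the submitters' processing notes, which give build mm9 and no versions. Thresholds and filters of the peak calling are not given in the sources used here.

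Each list gives a position and a score per peak, and all peaks of a list have 1 width, between 301 and 311 bp. The score is the authors' deposited value and its scale is not stated. Low scores (below 50) fell on whole multiples of a step that differed between lists, within the rounding of 1 decimal: 99.97%, 99.93%, 98.75% and 100.00% of scores in vehicle replicates 1 and 2 and forskolin replicates 1 and 2, where chance would give 43.1%, 44.6%, 41.9% and 14.5%. Such steps arise when tag numbers are scaled to a common total. If that holds, 1 tag was worth 0.232, 0.224, 0.239 and 0.688 score units, the depth of forskolin replicate 2 was 0.347 of that of forskolin replicate 1, both vehicle libraries were close to the latter (1.03 and 1.07), and a median peak held 47.8, 46.8, 62.0 and 21.1 tags. Because the assumption was not stated by the authors, scores were otherwise used only to rank peaks within a list, as percentiles, and no count model was fitted. The weighing of depth in the closing section rests on the assumption. Duplicate reads cannot be told from independent fragments here, so intervals cover counting error only.

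Regions were the union of all 4 lists, merged where peaks shared at least 1 bp. A region was forskolin-only with peaks in both forskolin and neither vehicle library, vehicle-only in the reverse case, and otherwise in all libraries or other. Library overlap was the share of peaks overlapping by at least 1 bp and the Jaccard index of bases. Peak numbers were compared with an exact permutation test. Shares have Wilson 95% intervals. Classes and gene lists were compared with two-sided Fisher's exact tests with conditional 95% intervals, which treat regions or genes as independent and describe these libraries rather than the spread between cultures. Benjamini-Hochberg adjustment ran over the 10 gene lists and, separately, over the 66 motif tests, with a threshold of 0.05.

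The reference was NCBIM37 with GENCODE M1 genes, the build named mm9 elsewhere, and every region fitted its chromosome on all 21 chromosomes. Distances run from a region's centre to the nearest 5' end of any transcript of a protein-coding gene, of which 22225 were annotated. Genes were assigned regions within 10 kb of a TSS, and the background of each list test was the 12264 genes with a region of any class there. Motifs were searched on both strands within 100 bp of the centre and in windows of the same size 2 kb to either side that overlapped no region. The motifs were the full CRE (TGACGTCA), its core (TGACG), AP-1 (TGAGTCA), RUNX (TGTGGT), CCAAT, E-box, GC box, C/EBP, a C/EBP-ATF composite, NRF1 and ETS sites. Copies of the highest-scoring regions were sought with BLAST 2.17.0. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

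The gene lists and the rule for named genes were set before the data were examined, and so were the tests and alternatives except those named in the closing section as chosen later. Among motifs, this holds for the full CRE, its core, AP-1 and RUNX. For the other motifs and the search for copies, no such prior choice is recorded. The 10 lists were CREB and cAMP immediate targets, PTH-responsive genes, osteoblast lineage and matrix, core CREB housekeeping targets, glycolysis and amino acid transport, the circadian clock, and markers of adipocytes, chondrocytes, skeletal muscle and haematopoietic cells or osteoclasts. Icer, Cebpd and Rankl matched no protein-coding gene symbol of the annotation (Rankl is Tnfsf11, which is in the list). Per1 and Per2 stand in 2 lists. The rule named up to 20 genes of the first 3 lists with a forskolin-only region within 10 kb, ordered by the lower of the 2 forskolin percentiles, out of 25 such genes. It also named the 10 genes within 1 kb of the highest-ranked forskolin-only regions, the 5 nearest to the highest-ranked vehicle-only regions, the 5 nearest to those of all libraries, and Fos, Nr4a1, Per1, Crem, Tnfsf11, Sost, Mmp13 and Runx2, which made 44 genes in all. Other list members are named where a count of members is given. A gene picked by the rule and a list member are not reported here.

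The merging and class rules were run on simulated lists, in which 25976 of 25976 regions fell into their simulated class. That result checks only that the rules were applied as written, and does not show how they treat closely spaced peaks. In the real lists, joining peaks within 500 bp changed the vehicle-only count from 125 to 61 and the forskolin-only count from 5187 to 5081. For the list test, simulated among the same 12264 genes, a planted list of 30 genes with forskolin-only regions at a share of 0.4 was called in 31 of 50 draws (62.0%), and random lists of 30 genes were called in 2 of 450 draws (0.4%). The size of the simulated list was lowered after earlier runs, in which larger lists were called more often. Alternatives were other rules for overlap and joining, fixed peak widths, the top 50% of each list, the same number of peaks from each list, other distance windows and backgrounds, and leaving out each library in turn.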

Results

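Phospho-CREB occupancy was mapped by chromatin immunoprecipitation and sequencing in MC3T3-E1 cells, a mouse pre-osteoblast line. The cells had been treated for 1 h with 100 nM forskolin, which activates adenylyl cyclase and so raises cAMP, or with DMSO vehicle. The antibody was raised against CREB phosphorylated at serine 133, the residue modified by protein kinase A. Parathyroid hormone (PTH), the subject of the series, acts on bone cells largely through the same cAMP pathway, and the comparison asked where phosphorylated CREB was found once that pathway was switched on. Each treatment had 2 libraries, given as biological replicates, and 1 peak list per library was analysed. The lists hold a position and a score per peak and no read totals, so the sequencing depth is not known directly. Regions were called forskolin-only when both forskolin libraries and neither vehicle library had a peak there, and vehicle-only in the reverse case. Coordinates are in the mouse build mm9 (NCBIM37).

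Forskolin libraries held more phospho-CREB peaks than vehicle libraries, 25566 and 19371 against 14686 and 10180. The means were 22468.5 ± 4381 and 12433 ± 3186 (SD, n = 2 each), a ratio of 1.81. Merging the 4 lists gave 28335 regions, of which 5187 (18.3%, Wilson 95% interval 17.9 to 18.8) were forskolin-only and 125 (0.44%, 0.37 to 0.53) vehicle-only. A further 8930 regions (31.5%, 31.0 to 32.1) had a peak in all 4 libraries. Of the 9452 regions shared by both vehicle libraries, 94.5% (94.0 to 94.9) were also called in both forskolin libraries, so sites occupied under vehicle were largely called again under forskolin. The converse did not hold, as 29.6% (28.9 to 30.3) of the 17536 regions of both forskolin libraries had no vehicle peak. Part of this is forced by list length, since only 15413 regions had a peak in either vehicle library.

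By the Jaccard index of bases, the 2 libraries of a treatment overlapped more than libraries of different treatments. It was 0.465 between the vehicle libraries and 0.481 between the forskolin libraries, and 0.302 to 0.402 between treatments. The share of overlapping peaks did not follow treatment in the vehicle lists. Of the peaks of vehicle replicate 1, 93.0% overlapped forskolin replicate 1, the longest list, and 64.0% vehicle replicate 2, and of those of vehicle replicate 2, 95.7% overlapped forskolin replicate 1 and 92.3% vehicle replicate 1. Among other ways of parting the 4 libraries into pairs, the largest count of regions found in both of 1 pair and neither of the other was 1430, for the replicates numbered 1 against those numbered 2. With 2 libraries against 2, an exact two-sided permutation test of the peak number gave p = 0.333, the smallest value that this design allows. With the top 50% of each list by score the counts were 2936 forskolin-only and 46 vehicle-only. With the 10180 top-scoring peaks of each list they were 1551 and 1064. Equal lists push both counts towards balance by construction. The longer forskolin lists push the main and top 50% counts apart in the same way. The size of the excess thus depends on list length, and no setting gives it free of this. Leaving out a library loosens the class rule and so can only raise both counts. Without forskolin replicate 2 there were 11351 forskolin-only regions, and without vehicle replicate 1 there were 8203. The vehicle-only count was 188 without forskolin replicate 2, 459 without forskolin replicate 1, 265 without vehicle replicate 1 and 796 without vehicle replicate 2.

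**Figure D1:**
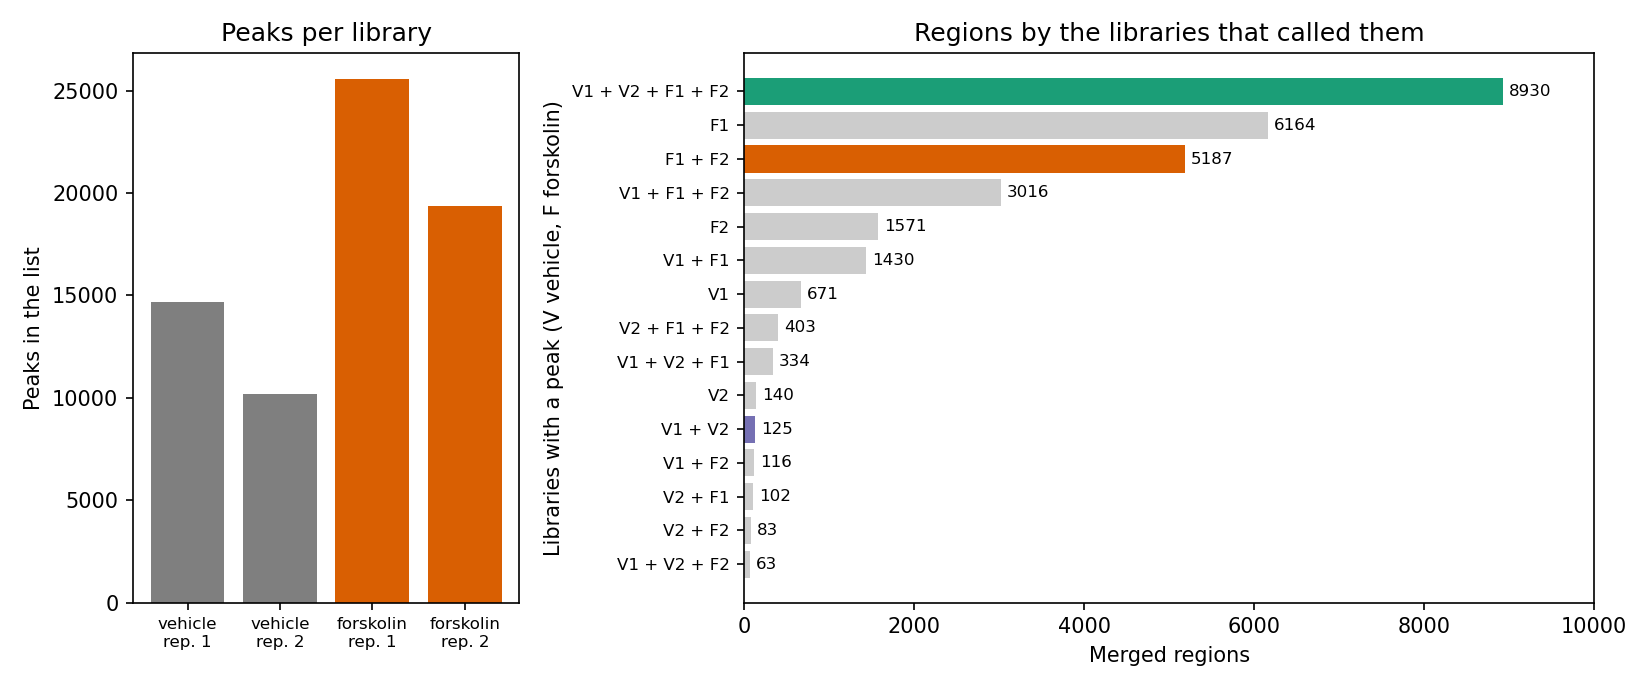
Left, number of peaks in each of the 4 lists (grey, vehicle; orange, forskolin). Right, number of merged regions for each combination of libraries with a peak; the forskolin-only class (orange) holds 5187 regions, the vehicle-only class (purple) 125 and the class of all libraries (green) 8930.

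Fos and Crem had phospho-CREB regions of all 4 libraries and, close by, further forskolin-only regions. Fos, which encodes an AP-1 subunit, had a region of all 4 libraries at its promoter (chromosome 12, 86814568 to 86814903, intergenic, -104 bp from a transcription start site, TSS; negative values are upstream). A forskolin-only region lay at -5010 bp (86809662 to 86809997, intergenic), within the top 5% of both forskolin lists at score percentiles 96.3 and 95.2. Within 100 kb of Fos there were 6 forskolin-only regions and 5 of all libraries. Crem encodes CREB-family regulators, among them the inducible repressor ICER, which is made from an internal promoter. It had a forskolin-only region in an intron at -71 bp from an annotated internal TSS (chromosome 18, 3281677 to 3281998), with a full CRE and score percentiles of 96.9 and 95.5. Regions of all 4 libraries lay at other TSS of Crem, 3280944 to 3281266 and 3337402 to 3337729, both in exons. When peaks within 500 bp were joined, the forskolin-only region of Crem merged with the first of these and was no longer counted.

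Nr4a1 and Per1 had no forskolin-only region within 10 kb of a TSS, and their promoters were called under vehicle as well. Nr4a1, a nuclear receptor induced by PTH and cAMP, had regions of all 4 libraries at -32 bp (chromosome 15, 101097080 to 101097409) and at -6286 bp (101090823 to 101091159), both intergenic. Their ranks differed between treatments. The region at -32 bp had percentiles of 77.4 and 62.6 in the vehicle and 96.1 and 94.2 in the forskolin lists. That at -6286 bp had 7.7 and 36.9 against 96.8 and 94.1. The 3 forskolin-only regions of Nr4a1 lay farther out, and the one at 12909 bp downstream (101110016 to 101110355) held a full CRE. Per1, a circadian clock component, had regions of all 4 libraries at -249 bp (chromosome 11, 68908305 to 68908634, intergenic) and at -6620 bp (68901817 to 68902380, exon). The former ranked alike, at 97.5 and 97.1 in the vehicle and 98.4 and 97.3 in the forskolin lists. The latter was mixed, at 68.8 and 26.9 against 58.9 and 73.1. The Per1 region with a full CRE (68910548 to 68910872, intron) was called in both forskolin libraries and in vehicle replicate 1.

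**Figure D2:**
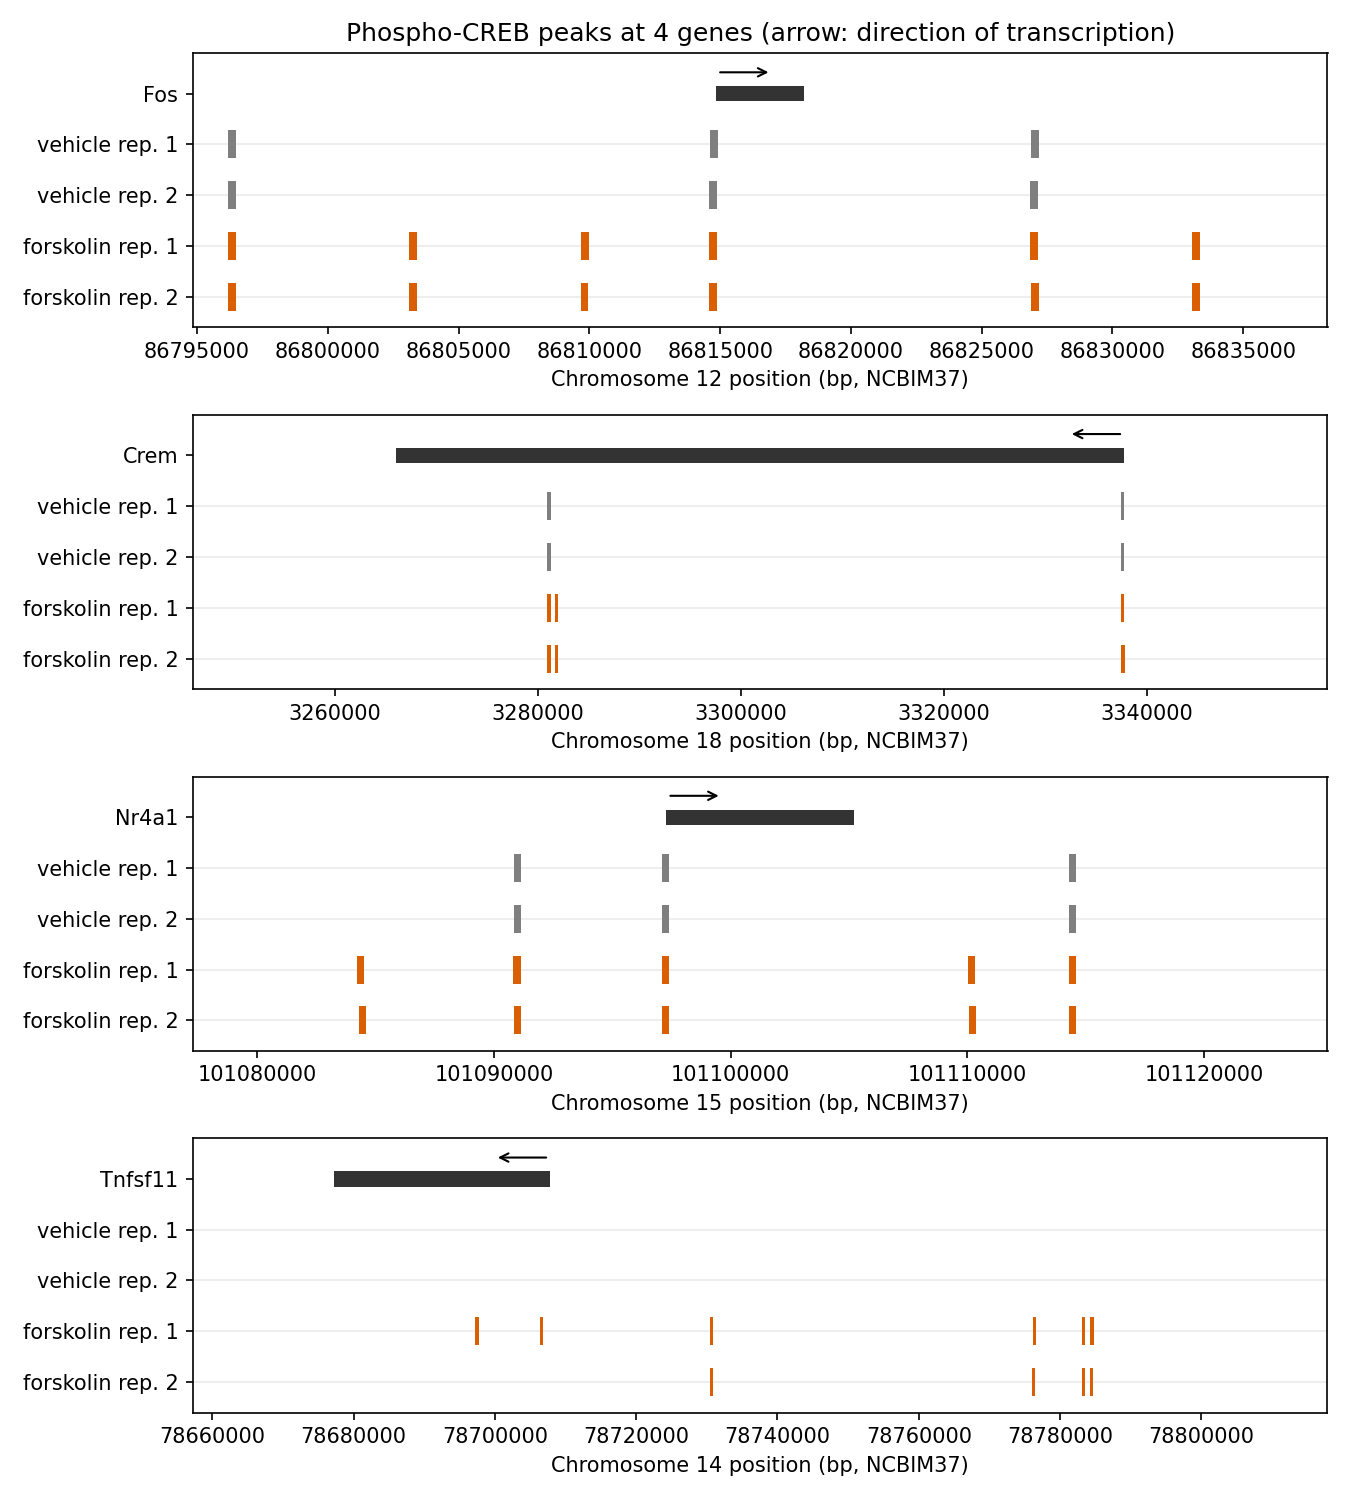
Peaks of each library around Fos, Crem, Nr4a1 and Tnfsf11, drawn to scale along the chromosome in bp (grey, vehicle; orange, forskolin; black bar, gene from first to last annotated base; arrow, direction of transcription). Very narrow peaks are widened to stay visible. The forskolin rows hold peaks with no vehicle counterpart, such as those at -5010 bp from Fos and upstream of Tnfsf11.

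Genes of the preset list of CREB and cAMP immediate targets lay near forskolin-only regions more often than other genes. Of its 42 annotated members, 39 had a region of any class within 10 kb of a TSS, and 16 of these (41.0%) had a forskolin-only region, against 1974 of 12264 genes (16.1%). The odds ratio was 3.65 (95% interval 1.8 to 7.23, two-sided Fisher's exact p = 0.000176, adjusted p = 0.00176 over 10 lists). The 16 were Fos, Jun, Egr1, Egr2, Crem, Cebpb, Nfil3, Bdnf, Ier2, Ier3, Gadd45b, Dusp1, Crtc1, Pde4b, Pde4d and Pde10a, and 7 of them had no region of all 4 libraries within that distance. A region of all 4 libraries lay within that distance of 28 of the 39 members, and of 8331 of the 12264 genes. Gadd45b, a stress-response gene, had one of the higher-ranked of these forskolin-only regions (chromosome 10, 80398615 to 80398941, intergenic, 5942 bp downstream of a TSS, percentiles 97.7 and 93.7). For the cAMP-degrading phosphodiesterases, the region of Pde10a lay between genes at -360 bp from a TSS. That of Pde4b lay in an exon, 143 bp downstream of an internal TSS. That of Pde4d lay in an intron, at -3248 bp from an internal TSS. Nfil3, which encodes a repressor with a basic leucine zipper, had a region at -1022 bp with percentiles of 87.0 and 86.8.

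The call for this list was not kept under every setting. It was lost with a 1 kb window (odds ratio 2.59, adjusted p = 0.416, Fisher's exact test) and when genes were compared within strata of their number of regions (Mantel-Haenszel odds ratio 2.3, 1.13 to 4.66, adjusted p = 0.154), the latter chosen after seeing the data. Over all alternatives the adjusted p ran from 2.51e-06 to 0.416. The tests compare genes within these libraries and carry no replicate error. With the shortest list's number of peaks taken from each list, 10 members had a forskolin-only region, while Jun, Egr2, Bdnf, Ier3 and Crtc1 had 0, as did Alpl and Mmp14 of the bone lists.

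For PTH-responsive genes of osteoblasts and osteocytes, the share with a forskolin-only region was close to that of all genes with a region. Of the 25 list members with a region within 10 kb, 4 had a forskolin-only region (16.0% against 16.1%, odds ratio 0.993, 0.248 to 2.95, adjusted p = 1, Fisher's exact test): Mmp14, Lif, Fst and Lrp6. Lrp6, a Wnt co-receptor, had its region in an intron at -2121 bp (chromosome 6, 134423251 to 134423613), and Mmp14, a membrane-bound collagenase, in an intron 2097 bp downstream (chromosome 14, 55052373 to 55052703). The list's odds ratio was 3.54 without forskolin replicate 2 (adjusted p = 0.0161), 2.28 without forskolin replicate 1 (adjusted p = 0.308) and 5.0 with equal lists (adjusted p = 0.166, Fisher's exact test). Within 100 kb, 20 of the 31 members had a forskolin-only region (odds ratio 1.83, adjusted p = 0.364, Fisher's exact test).

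Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, had no region of both forskolin libraries within 10 kb of a TSS. All 4 of its forskolin-only regions within 100 kb lay upstream and between genes on chromosome 14, at -22725 bp (78730419 to 78730730), -68368 bp (78776027 to 78776408), -75375 bp (78783067 to 78783382) and -76544 bp (78784227 to 78784560). The first and last ranked high, at percentiles 94.9 and 94.5 and at 93.3 and 94.2 in the forskolin lists, and no region of all 4 libraries lay within 100 kb. Sost, encoding the Wnt inhibitor sclerostin, had 1 forskolin-only region and 1 region of all 4 libraries within 100 kb, the former 85361 bp downstream in an intron (chromosome 11, 101742793 to 101743142) and at percentiles of only 8.0 and 5.3. Mmp13, a collagenase of bone, had 0 forskolin-only regions within 100 kb.

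Among 22 osteoblast lineage and matrix genes with a region, 5 had a forskolin-only region (22.7%, odds ratio 1.53, 0.442 to 4.34, adjusted p = 0.682, Fisher's exact test): Runx2, Sp7, Alpl, Sparc and Dlx5. Runx2, the master transcription factor of osteoblasts, had 2 of them and no region of all 4 libraries within 10 kb. The first lay in an intron at -2056 bp from a TSS (chromosome 17, 44875489 to 44875817) and held both a full CRE and an AP-1 site. The second covered a TSS in an exon at -15 bp (44951346 to 44951836), at percentiles of 80.8 and 47.5 and without a CRE core. Runx2 kept 1 of the 2 when at least 50% of the shorter peak had to overlap, and also with the top 50% of each list. Alpl, the bone alkaline phosphatase, had 3 forskolin-only regions within 10 kb, the highest-ranked at -1825 bp in an intron (chromosome 4, 137304724 to 137305050). Dlx5, a homeobox activator of the lineage, had 1 at -2842 bp (chromosome 6, 6834764 to 6835090, intergenic) and Sparc, encoding the matrix protein osteonectin, 1 in an intron 5282 bp downstream (chromosome 11, 55227949 to 55228286).

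Housekeeping genes of the list preset as CREB promoter targets had promoter regions under both treatments. All 24 core CREB housekeeping targets, among them Pcna, Hspa5 and Cycs, had a region of all 4 libraries within 1 kb of a TSS. So had 6747 of the 12264 genes with any region within 10 kb. Of the 24, 0 had a forskolin-only region within 10 kb (odds ratio 0, 0 to 0.865, Fisher's exact p = 0.0241, adjusted p = 0.12). Within 100 kb, 13 had one (odds ratio 1.19). The difference at 10 kb did not pass the adjusted threshold, except without vehicle replicate 1 (adjusted p = 0.00434, Fisher's exact test). Glycolysis and amino acid transport genes had a forskolin-only region in 3 of 16 cases (Gapdh, Ldha and Slc7a5; odds ratio 1.2, adjusted p = 0.917) and clock genes in 4 of 13 (Arntl, Dbp, Bhlhe41 and Rora; odds ratio 2.32, adjusted p = 0.402, Fisher's exact test). Among markers of other cell types, 3 of 10 adipocyte, 7 of 10 chondrocyte, 1 of 10 skeletal muscle and 4 of 10 haematopoietic or osteoclast genes had a region of any class within 10 kb, against 12264 of all 22225 genes. Adipoq of the adipocyte, Sox9 of the chondrocyte and Myh3 of the muscle list had a forskolin-only region, and over the 4 lists the adjusted p ran from 0.402 to 1 (Fisher's exact test).

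The highest-ranked forskolin-only region within 1 kb of a TSS lay at -98 bp from Cirbp, which encodes a cold-inducible RNA-binding protein (chromosome 10, 79628474 to 79628789, intergenic). Its deposited scores were 289.3 and 154.2, at percentiles 99.8 and 99.6 of the forskolin lists, and it held the CRE core TGACG and an AP-1 site. Next came Gm10463, a predicted gene (-620 bp, chromosome 5, 32436001 to 32436320), then Crem and A730049H05Rik. Others in the highest 10 were Eprs, a tRNA synthetase, Mogat1, an enzyme of lipid synthesis, Aqp1, a water channel, and Tgif1, a homeobox repressor, along with Rabgef1 and A330021E22Rik. Of these 10 regions, 9 held the CRE core within 100 bp of the centre. Cirbp, Aqp1 and A330021E22Rik each also had 1 vehicle-only region within 10 kb, as had 92 of the 12264 genes. The region of Aqp1 was no longer separate when peaks within 500 bp were joined.

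Both treatment-specific classes ranked below regions of all 4 libraries within the same lists. Regions called in every list tend to be strong, so this ranking is in part built into the classes. Median score percentiles were 44.6 and 32.0 for forskolin-only against 77.2 and 70.4 for all-library regions in the forskolin lists. In the vehicle lists they were 41.6 and 26.9 for vehicle-only against 67.3 and 55.1. Among the highest-ranked vehicle-only regions were those nearest to Opa3, Pcbp1, Zfp91 and Mat2a, with percentiles between 80.1 and 96.3 in the vehicle lists. The one at Opa3, a mitochondrial membrane protein gene, lay 362 bp inside the gene in an intron (chromosome 7, 19813940 to 19814247). Among regions of all 4 libraries, the 5 highest-ranked were nearest to Gm10800, Gm5614, Cdk8, Osbp and Axin2. The region at Gm10800 (chromosome 2, 98507134 to 98507444, exon) matched 152 further places in the reference and that near Gm5614 (chromosome 9, 35112883 to 35113193, intergenic) matched 149, each at 90% identity or more over 200 bp or more. How reads that map to several places were treated is not given in the sources used here. The other three had 0 further matches. Osbp, an oxysterol-binding protein gene, had its region at -297 bp (chromosome 19, 12039863 to 12040210) with a CRE core.

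Forskolin-only regions lay mostly away from promoters, while regions of all 4 libraries lay mostly at them. Within 1 kb of a TSS of a protein-coding gene were 12.9% (Wilson 95% interval 12.1 to 13.9) of forskolin-only regions, 40.0% (31.8 to 48.8) of vehicle-only regions and 67.0% (66.0 to 68.0) of regions of all 4 libraries. The odds ratio of forskolin-only against all-library regions was 0.0731 (0.0666 to 0.0803, Fisher's exact test). Of all forskolin-only regions, 39.0% lay in introns and 45.5% between genes, counting only those farther than 1 kb from a TSS. A share of 64.1% was over 10 kb from any TSS. Regions of 1 library were placed much like them, 18.3% within 1 kb of a TSS and 60.2% over 10 kb away, so a distal position is not particular to forskolin-only regions. Median distances to the nearest TSS were 19419 bp for forskolin-only, 3425 bp for vehicle-only and 141 bp for all-library regions. The odds ratio stayed below 1 in each alternative, at 0.131 with a 5 kb window, 0.131 without vehicle replicate 1 and 0.121 without vehicle replicate 2.

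**Figure D3:**
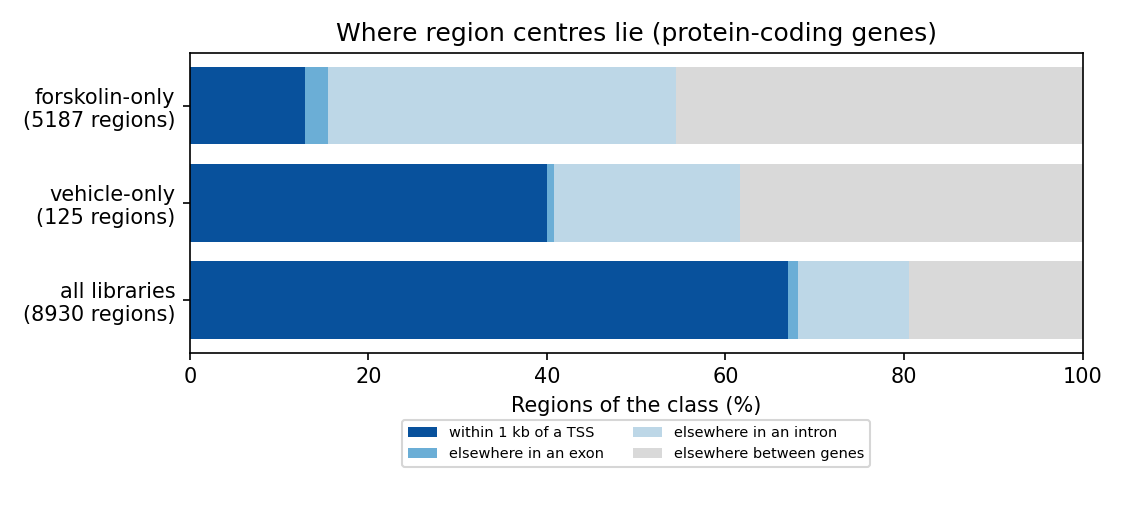
Share of regions of each class (percent, horizontal axis) by the position of the region's centre relative to protein-coding genes. Forskolin-only regions are within 1 kb of a TSS in 12.9% of cases, against 67.0% for regions of all libraries.

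Both classes with forskolin peaks carried the sequence that CREB binds. The full cAMP response element (CRE, TGACGTCA) lay within 100 bp of the centre of 3.59% (3.11 to 4.13) of forskolin-only regions and 0.14% of windows 2 kb away. That is an odds ratio of 26.7 (15.5 to 49.9, Fisher's exact adjusted p = 1.58e-69 over 66 motif tests). The ratio was 44.6 within 50 bp, 11.9 within 250 bp and 16.8 without vehicle replicate 1. Regions of all 4 libraries held it in 6.64% (6.14 to 7.18) of cases, more often than forskolin-only regions (odds ratio 0.523 for forskolin-only, 0.439 to 0.62, Fisher's exact adjusted p = 1.06e-14). Of the vehicle-only regions, 0 of 125 held it, which allows a share of up to 2.98% (Wilson).

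The CRE core TGACG was present in 38.6% (37.3 to 39.9) of forskolin-only regions, 39.3% (38.3 to 40.4) of all-library regions and 12.8% (8.03 to 19.8) of vehicle-only regions, against 6.39%, 6.18% and 5.88% of windows 2 kb away. Forskolin-only and all-library regions did not differ overall (odds ratio 0.97, 0.903 to 1.04, Fisher's exact p = 0.4, adjusted p = 0.529), but this value mixes opposite differences. Farther than 1 kb from a TSS, forskolin-only regions held the core more often (39.3% against 32.3%, odds ratio 1.36, 1.23 to 1.5), a split chosen after seeing the data, and within 1 kb less often (34.0% against 42.8%, odds ratio 0.688, 0.579 to 0.816). Within 250 bp of the centre the overall ratio was 0.813, and it was 1.16 without vehicle replicate 2 but 0.671 without forskolin replicate 2. Against vehicle-only regions the ratio of forskolin-only regions was 4.28 (2.51 to 7.78, Fisher's exact adjusted p = 1.33e-09). In classes rebuilt from 10180 peaks per list, also chosen after seeing the data, the core lay in 58.9% (56.5 to 61.4) of 1551 forskolin-only, 49.3% (48.0 to 50.5) of 5912 all-library and 13.3% (11.4 to 15.5) of 1064 vehicle-only regions (odds ratio of forskolin-only against vehicle-only 9.32, 7.57 to 11.5). Most of these vehicle-only regions had a forskolin peak below the cut, as in the full lists only 125 regions of both vehicle libraries had none. The cut also removed more of the forskolin lists. The ratio of 9.32 therefore sets top-ranked forskolin peaks against a larger part of the vehicle lists, and is not a treatment difference alone.

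**Figure D4:**
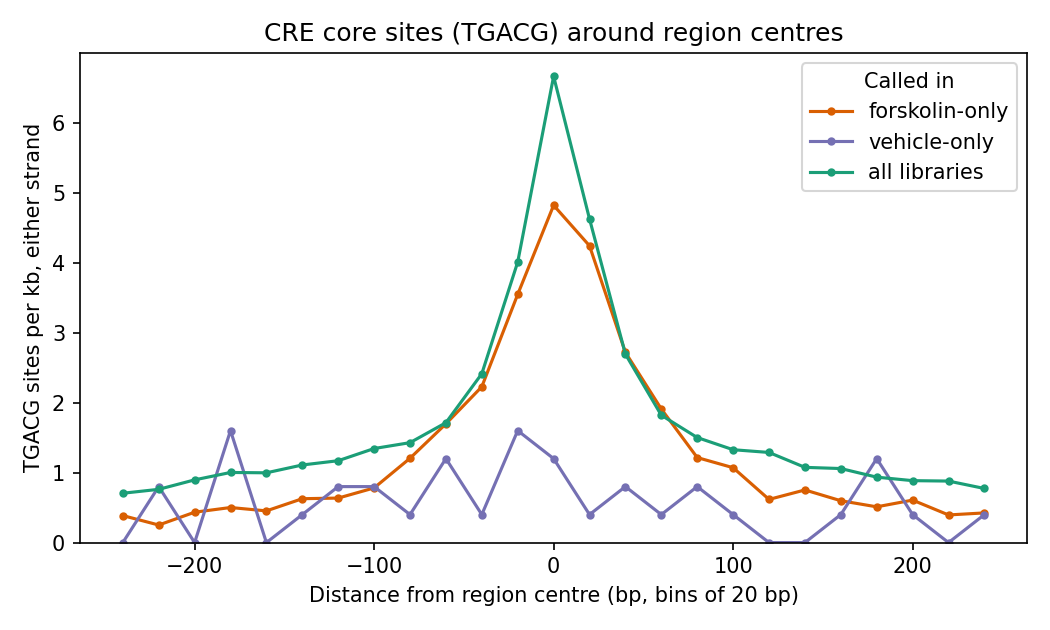
Density of the CRE core TGACG on either strand (sites per kb, in bins of 20 bp) against the distance from the region centre in bp. In the bin at the centre the density is 4.82 per kb in forskolin-only and 6.66 per kb in all-library regions, and the vehicle-only line rests on 125 regions.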

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

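Tests chosen only after the results were seen were those of depth and of neighbouring forskolin peaks, the GC strata of the CRE core, AP-1 and RUNX, the Mantel-Haenszel strata, the 1 kb neighbour rules, the restriction to distal regions, the class comparison with equal lists, the test of immunoprecipitation efficiency and the alternatives for library overlap. Every alternative run kept the direction of the peak number difference (10035.5 peaks; 6938 to 13133 with a library left out), of the location odds ratio (0.0805 to 0.131) and of full CRE enrichment over windows 2 kb away. Whether same-numbered libraries share a culture is not given by the labels, and they were treated as unpaired. Over 28335 regions, deviations of same-numbered libraries had a correlation of 0.05, but 2 pairs cannot settle the question. With a replicate block the mean difference was again 10035.5 peaks (10880 and 9191 per pair; smallest possible exact p = 0.5) and the region counts are identical by construction (5187 forskolin-only). A common score threshold across lists was not run, because the scale of the score is not stated.

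The top 50% of each list gave 2936 forskolin-only, 46 vehicle-only and 4329 all-library regions, and 10180 peaks per list gave 1551, 1064 and 5912, where equal lists push the first and second towards balance by construction. In the main setting and with the top 50%, the longer forskolin lists push forskolin-only above vehicle-only counts. Joining peaks within 500 bp gave 61 vehicle-only regions. Of the 125 vehicle-only regions of the main setting, 57 had no forskolin peak centre within 1 kb. Of the 5187 forskolin-only regions, 4957 had no vehicle peak centre within 1 kb. Leaving out 1 library gave 5590 to 11351 forskolin-only, 188 to 796 vehicle-only and 8993 to 11946 all-library regions. Of 31 named genes with a forskolin-only region, 23 kept one with equal lists. Leaving out a library loosens the class rule, so no forskolin-only region can be lost there.

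For gene lists, 1 was called, against 0 with a 1 kb window and 0 with Mantel-Haenszel strata, and 1 to 2 with a library left out. The CREB list had odds ratios of 2.59 and 2.3 in the first and second case and 2.66 to 3.47 with a library left out. No other list was called in the main test, but the PTH-responsive list was without forskolin replicate 2 (adjusted p = 0.0161) and the housekeeping list without vehicle replicate 1 (adjusted p = 0.00434, Fisher's exact tests). The lists named below crossed an odds ratio of 1 in places, and the cause was not tested. With a 1 kb window the ratio was 0 for glycolysis, clock, adipocyte and haematopoietic lists and 4.44 for chondrocyte markers. With 100 kb it was 1.83 for PTH-responsive, 1.19 for housekeeping, 4.02 for chondrocyte and 0.803 for haematopoietic genes. With equal lists it was 5.0 for PTH-responsive, 16.6 for chondrocyte and 0 for adipocyte and haematopoietic genes. With all genes as background it was 1.52 for PTH-responsive and 1.14 for chondrocyte genes, the latter 1.21 with strata. With a library left out, ranges were 0.979 to 3.54 (PTH-responsive), 0 to 0.65 (housekeeping), 0.839 to 1.63 (glycolysis), 0.745 to 4.24 (chondrocyte) and 0.839 to 2.12 (haematopoietic).

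The CRE core ratio of forskolin-only against all-library regions, 0.97, was 0.813 within 250 bp of the centre, 1.36 in distal regions only, and 0.671 to 1.16 with a library left out. With strata of GC content it was 1.09 (1.01 to 1.18), with the core more frequent in forskolin-only regions at low GC content and less frequent at high GC content. Forskolin replicate 2 had the lowest depth, if score steps reflect tags, and how far depth limited the calling of weak peaks was not tested.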

Other observations

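Some genes were nearest to several forskolin-only regions, and those named here were picked after their counts were seen. Zfp608 was the nearest gene of 10 forskolin-only regions and of 11 regions of all 4 libraries. Foxc2, Slit3 and Zfp36l1 were nearest to 9 each, with 2 all-library regions each, and Runx2 to 9, with 3. Sox9, the chondrocyte regulator, and Maf had 7 each, and Auh and Rin2 had 7 with 0 all-library regions. Runx2 and Sox9 are members of the preset lists. The counts were neither tested nor adjusted for the length of sequence nearest to each gene.

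Promoter motifs were more frequent in regions of all 4 libraries than in forskolin-only regions, most strongly ETS sites. ETS sites (CCGGAAGT) lay in 7.09% of all-library and 0.40% of forskolin-only regions (odds ratio 0.0533, 0.0327 to 0.0823), GC boxes in 39.1% and 9.79%, E-boxes (CACGTG) in 8.05% and 3.43%, and CCAAT boxes in 31.7% and 23.2%. In windows 2 kb from all-library regions the shares were 0.15%, 3.00%, 2.37% and 23.5%. GC boxes were also more frequent in forskolin-only regions than in windows 2 kb from them (3.47%, odds ratio 3.02, 2.62 to 3.48). The median GC content was 59.7% in all-library and 49.3% in forskolin-only regions.

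In the weighing that follows, the tests of depth, of immunoprecipitation efficiency and of neighbouring forskolin peaks were chosen after the results were seen, and so were the GC strata of AP-1 and RUNX and the restriction of AP-1 to distal regions.

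The first pattern is the excess of 5187 forskolin-only over 125 vehicle-only regions. Its size depends on list length, with 1551 over 1064 when each list gave 10180 peaks. Deeper sequencing of the forskolin libraries is argued against by forskolin replicate 2, whose list was 1.32 times as long as the longer vehicle list although the score steps put its depth lowest, if these steps reflect tags scaled to a common total. The full CRE, with an odds ratio of 26.7 over windows 2 kb away, shows that the class holds CREB-type sites. It cannot decide whether their absence from the vehicle lists was chance, since sites missed there by chance would hold it too. It lay in only 3.59% of the regions, and the other class was also enriched (1.57% against 0.14%). A more efficient immunoprecipitation cannot be told apart from a rise of phospho-CREB on forskolin. The CRE core was more frequent than in regions of both forskolin and 1 vehicle library (Mantel-Haenszel odds ratio 2.09, 1.89 to 2.32), which better enrichment of specific sites would also give. The full CRE was rarer than in all-library regions, as for weaker sites of the same kind. Score percentiles were lower too, but cannot decide, since regions called in every list tend to rank higher under either explanation. Both stay open.

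The second pattern is the 125 vehicle-only regions. A region of both forskolin libraries lay within 10 kb of 82.4% (Wilson 95% interval 74.8 to 88.1) of them, against 60.0% (56.6 to 63.4) of regions of a single vehicle library, an odds ratio of 3.11 (1.9 to 5.29, Fisher's exact test). The classes compared were not matched for distance to a TSS. A candidate explanation is that a peak weaker than its surroundings was passed over in the forskolin lists. Joining peaks within 500 bp left 61 vehicle-only regions, and only 57 of the 125 had no forskolin peak centre within 1 kb. Part of the class thus depends on how closely spaced peaks were joined. The full CRE cannot tell whether the regions are chance calls or real sites. It lay in 0 of 125 regions, an odds ratio of 0 (0 to 74.3) over windows 2 kb away. The core was more frequent than in those windows (odds ratio 2.35, 1.03 to 5.39, Fisher's exact adjusted p = 0.0482). GC boxes differed more (23.2% against 2.10%, odds ratio 14.1, 5.14 to 47.6). The windows were not matched for GC content or distance to a TSS, so the core cannot decide this either. A loss of phospho-CREB on forskolin stays open and was not tested.

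The third pattern is the sequence of forskolin-only against all-library regions, and as a hypothesis forskolin-only sites may be enhancers that AP-1 factors also bind. AP-1 sites (TGAGTCA) lay in 21.8% of forskolin-only and 6.17% of all-library regions (odds ratio 4.25, 3.8 to 4.74), but farther than 1 kb from a TSS in 23.4% and 14.0% (odds ratio 1.88, 1.66 to 2.14). RUNX sites (TGTGGT) lay in 33.4% and 15.9% (odds ratio 2.66, 2.45 to 2.89), with 36.9% and 34.4% among the regions lowest in GC content, 33.2% and 18.2% in the middle stratum and 13.3% and 7.5% in the highest. Part of the RUNX difference thus went with GC content, and whether GC content is its source stays open. Within strata of GC content the ratios were 2.57 (2.29 to 2.89) and 1.57 (1.43 to 1.71), and lower GC content did not account for the fewer full CREs, whose stratified ratio was 0.566 (0.468 to 0.684). AP-1 sites were also frequent, at 15.9%, in regions of the remaining class, so binding of these factors and a general feature of accessible distal chromatin both stay open, and a motif is no measurement of binding.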
